A study of Oryza sativa with 4 samples.

How the data were processed

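Ribosome profiling sequences the stretches of mRNA that ribosomes cover, so that its reads count translating ribosomes. Per the labels' protocols, shoots of rice plants 2 weeks old were immersed in water at 22 °C or at 42 °C for 10 min, and 4 footprint libraries were made, 2 for each temperature, described as biological replicates. Footprint reads were processed with cutadapt and Bowtie2, per the submitters' processing notes, which give no version in the sources used here. The genome build and the transcript annotation are not given in the sources used here.

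The deposited table lists 14122 rice transcripts, each with a description, a score at each temperature and the difference of both scores. Per the file headers the score columns carry only the temperature. The score is read here as translational efficiency, footprints relative to RNA, because the series' design text gives that as the purpose of the libraries; no header states the formula, the scaling or a log step. A linear ratio and log(1 + ratio) cannot be told apart from the scores. Either reading keeps the direction of a difference, and under the log reading a ratio of 2 scores understates the change. In all 14122 transcripts the deposited difference matched the score at 42 °C minus the score at 22 °C within 1e-05.

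The table holds 1 score per temperature, with no value per replicate, so there is no spread between replicates, no test of a difference between temperatures and no p-value. The depth of each library is unknown. Replicate similarity and footprint abundance were not analysed here. The plan fixed before the data were examined had assumed an abundance unit for such a table, with a minimum of 1 at both temperatures for calls and a mean of 5 for named genes. These minimums do not suit the scores, of which 136 genes have at least 1 at both temperatures and 6 have at least 5. Every gene above 0 at both temperatures was therefore used for calls, and the named genes needed a mean score of at least 0.234, the 75th percentile of genes. That replacement was chosen after the scores were seen.

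Transcripts were reduced to 10455 genes by averaging the scores of the transcripts of each locus, of which 2848 had more than 1. The log2 ratio of 42 over 22 °C was computed for the 9280 genes above 0 at both temperatures, and a gene was called higher or lower at a ratio of at least 2-fold. The 234 genes at 0 at 22 °C alone and the 480 at 0 at 42 °C alone have no fold and entered list medians as ranks, and 461 genes at 0 at both were left out. Kinds of protein are those of the table's own descriptions. Short names of genes fixed in advance that were not analysed here come from that plan, by locus. Word lists hold some genes of other kinds, which were found after the data were seen. The reference gene table for assembly ASM3414082v1 named 0 of the listed genes by locus, so neither its names nor its coordinates were used.

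Before the data were examined, 34 gene lists were fixed by words in the descriptions and by locus; 32 had at least 5 genes. The list of organelle-encoded genes had 0 members, and the reference genes had 3. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on the mean score in 20 bins of level. A list stands apart here when its median lies outside the 2.5th to 97.5th percentiles of its random lists. That describes these pooled scores and is no test across replicates. Intervals of a list's median are exact binomial 95% intervals over genes, which are not replicates. On simulated lists without a shift, 5.5% of 400 lists of 10 genes, 4.5% of 400 lists of 40 and 6.25% of 400 lists of 200 fell outside that range. With a simulated log2 shift of -1, 71 of 100 lists of 10 genes and 100 of 100 lists of 40 genes did. With a shift of -0.5 these were 22 and 91 of 100, so that most short lists with such a shift lay inside the range. The simulation reassigned ratios among single genes, so its lists hold no copies that share reads.

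The genes named are the 10 largest ratios in each direction with a description that says what the protein is, up to 3 members past 2-fold from each list that stands apart, and 15 genes fixed in advance, of which 10 were analysed. Other genes named were chosen after their scores were seen and are marked as such. Alternatives planned before the data were examined were other thresholds, minimum scores, each transcript on its own, centring on the median of all genes and lists by locus alone. Those added afterwards were minimum mean scores of 0.05 and 0.2, scores read as log2(1 + ratio), the lowest-numbered transcript of each gene, transcripts with the suffix 00 left out, 0.1 added to every score, AP2/ERF genes by domain, centring on genes with a mean of at least 0.2, and list members left out that are of another kind by description or match only through the name of a cDNA clone. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.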

Results

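Translation in rice shoots was profiled after 10 min in water at 22 °C or 42 °C, with 2 libraries at each temperature, to determine how translational efficiency differed between the temperatures. The deposited table gives 1 score per transcript and temperature, read here as translational efficiency. Scores were low and skewed: across genes above 0 at 1 or both temperatures the median was 0.0869 at 22 °C and 0.0803 at 42 °C, and the 90th percentile was 0.434 and 0.508. No value has a replicate, and the depth behind each is unknown, so differences below are ratios of 2 pooled scores, called by size alone.

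Most genes had scores within 2-fold of each other at both temperatures. Lists of cytosolic ribosomal proteins, HSP70 and chaperonins had medians below those of matched random lists, and lists of histones, WRKY factors and jasmonate genes had medians above. Of 9280 genes above 0 at both temperatures, 5783 (62.3%) lay within 2-fold, 1495 were at least 2-fold higher at 42 °C and 2002 at least 2-fold lower. The median log2 ratio was 0.03, with quartiles of -0.83 and 0.67. Across genes, which are not independent replicates, Spearman's rho between the temperatures was 0.844. The balance of calls depended on level: among the 10% of genes with the lowest mean scores 71.0% lay beyond 2-fold and the median log2 ratio was -0.68, against 11.6% and 0.29 in the highest 10%. Higher genes made up 42.8% of the calls, 60.7% among genes with a mean score of at least 0.2, and 30.04% when ratios were centred on the median of those genes, a shift of 0.27 on the log2 scale.

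**Figure D1:**
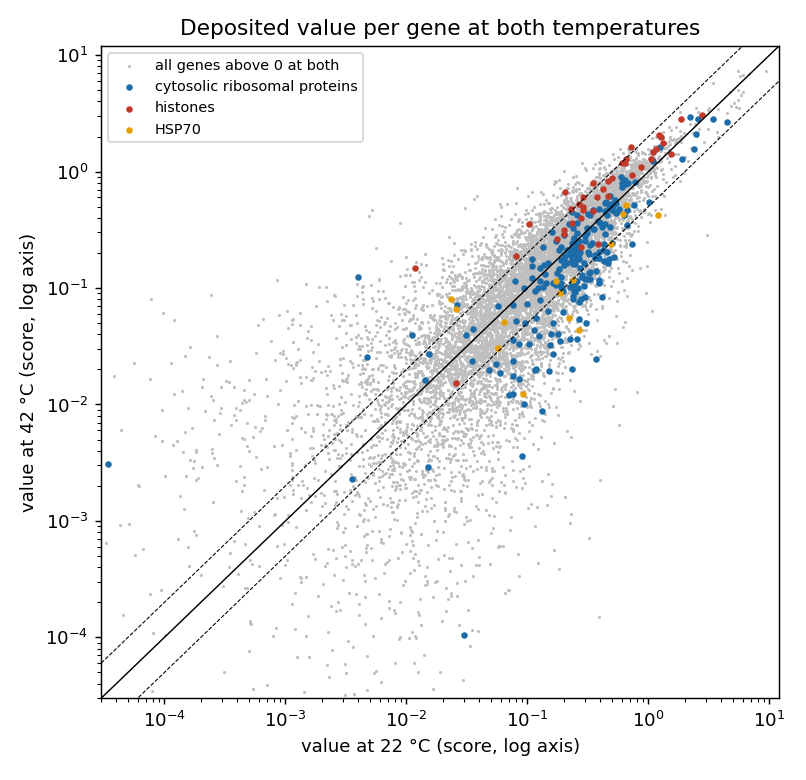
Score per gene at 22 °C (x) and 42 °C (y), both on log axes, for the 9280 genes above 0 at both temperatures that lie within the axes; the solid line marks equal scores and the dashed lines 2-fold. Cytosolic ribosomal protein genes (blue) lie mostly below the line and histone genes (red) mostly above it.

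Most cytosolic ribosomal protein genes had lower scores at 42 °C, whereas the word list for initiation factors did not stand apart. Of 217 genes in the list of cytosolic ribosomal proteins, 156 were lower and 61 higher, 71 at least 2-fold lower and 5 at least 2-fold higher. Their median log2 ratio was -0.49 (95% interval over genes -0.62 to -0.31), below all 10000 matched random lists, whose median was 0.15. The median was -0.23 among the 114 genes with a mean of at least 0.2, below all random lists of such genes. It was -0.76 when ratios were centred on all genes with such a mean, which moves random lists alike and leaves percentiles as they are. By description 7 of the 217 are of other kinds, and the remaining 210 had a median of -0.50. Some descriptions among the 217 name neither a subunit nor a compartment, so they do not show the gene to be cytosolic. Examples, named after their scores were seen, are Os01g0523401 (ribosomal protein S18, 4.44 and 2.69) and Os10g0214132 (ribosomal protein L2, 2.36 and 1.57). The largest ratios past the minimum were those of ribosomal protein L36 (Os03g0811800), from 0.410 to 0.0835, L11 (Os06g0550000), from 0.387 to 0.111, and S14 (Os04g0413600), from 0.389 to 0.117. Ribosomal protein genes have near-identical copies whose reads the table may divide between loci. Elongation factors include proteins that carry tRNAs to the ribosome or move it along. Their list of 14 genes, EF1B subunits among them, had a median of -0.85 (interval -1.60 to 0.51) at the 0.570th percentile. Of these 10 were lower, 6 of them at least 2-fold, and 4 higher. One of the lower genes, Os01g0268800 (0.0170 and 0.0144), is described only by a ubiquitin-associated/EF1B N-terminal domain and was named after its scores were seen. A gene described as EF1B/ribosomal protein S6 is in the ribosomal list too, and the EF-1 alpha loci may also divide reads. The elongation factor list moved inside the range, with a median of -0.52 at the 4.58th percentile, when only its 5 genes with a mean of at least 0.2 were used. The word list for initiation factors holds genes of other kinds by description. Among them, named after their scores were seen, are a heterochromatin protein (Os12g0607100) and a CASC3/Barentsz protein (Os05g0534600). No median without such genes was computed. The lists of initiation factors (32 genes, median -0.01, 46.9th percentile) and plastid ribosomal proteins (47 genes, -0.08, 5.33rd percentile) lay inside their ranges. Both medians turned positive without transcripts of suffix 00 (0.15 and 0.15) and at a mean of at least 0.05 (0.20 and 0.12) or 0.2 (0.30 and 0.23). With each transcript on its own the plastid list lay outside, at -0.13 (1.55th).

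Chaperones assist protein folding, and their lists differed in how firmly they stood apart. A rise in their RNA, the denominator, would lower these scores with footprints unchanged. Footprints and RNA are not given apart, so lower scores need not mean less translation of chaperones. Of 16 genes in the HSP70 list 13 were lower and 3 higher, with a median of -0.97 (interval -1.99 to -0.31) at the 0.270th percentile. The higher genes include Os08g0296900, described as a tetratricopeptide-like protein and named after its scores were seen (0.0259 and 0.0655). The HSP70 gene Os03g0277300 had 1.19 at 22 °C and 0.423 at 42 °C, and Os03g0276500 had 0.490 and 0.239. The word list for HSP100 disaggregases and chaperonins (16 genes, 12 lower, 4 higher) had a median of -0.68 (interval -2.28 to 0.10; 0.150th percentile), and of -1.07 without transcripts of suffix 00. It holds 3 RbcX proteins, described as chaperonin-like, without which 13 genes had -0.64 (0.350th). The RbcX protein Os03g0807900 went from 0.434 to 0.188 and the plastid 20 kDa chaperonin Os09g0438700 from 0.345 to 0.164. Os03g0426900, described as similar to HSP101 and named after its scores were seen, had 0.217 and 0.0446. The list of HSP90 and its partners (10 genes, 7 lower, 3 higher) had a median of -1.65 (interval -4.13 to 0.23; 1.31st percentile). It holds a phosphoinositide kinase, Os07g0573300, taken in by part of its description, and its other 9 genes had a median of -2.51 (0.450th percentile). That median is the ratio of 1 low-scored gene, Os09g0482400 (0.0281 and 0.00493). Os09g0482600 (0.0308 and 0.00537) has the same description, HSP81-3, so reads may be divided between them. Both were named after their scores were seen. The HSP82 gene Os08g0500700 had 0.103 and 0.00590. This list lay inside the range by fixed loci alone (6 genes, -1.65, 5.60th percentile), among its 5 genes with a mean of at least 0.05 (-0.79, 10.1st percentile) and with 0.1 added to the scores (-0.22, 5.60th). Small heat shock proteins (11 genes, 7 lower, 4 higher) had a median of -0.46 (interval -0.64 to 0.40; 0.770th percentile), with 10 genes within 2-fold, and of -0.72 when centred on genes with a mean of at least 0.2. It moved inside the range, with a median of -0.22, by fixed loci alone (5 genes, 4.70th percentile) and among the 9 genes with a mean of at least 0.2 (3.43rd percentile), and with 0.1 added to the scores (-0.20, 3.00th). The word list for DnaJ co-chaperones had 95 genes and a median of -0.38 (2.51st percentile), but 33 of them were taken in by the name of a cDNA clone alone. The other 62 had a median of -0.37 (3.05th percentile), inside the range. Over the word list the median was -0.05 (17.2nd) at a mean of at least 0.05 and turned to 0.31 (65.4th) over its 21 genes with a mean of at least 0.2. Folding genes of the endoplasmic reticulum lay inside it too (14 genes, -0.29, 29.6th percentile), with -0.04 (53.1st) without a katanin subunit, Os01g0683100. Their median turned positive with each transcript on its own (0.17, 76.9th), with the lowest-numbered transcript (0.07, 61.7th) and over the 7 genes with a mean of at least 0.05 (0.72, 94.9th). The lumenal binding protein gene Os02g0115900, an ER chaperone, had 0.0940 at 22 °C and 0.161 at 42 °C. The loci fixed in advance for HSP101 (Os05g0519700) and an HSP90 (Os04g0107900) were not analysed here.

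Regulators of the heat response went both ways. The list of DREB2 factors, which drive heat and drought genes, and of HSF-binding proteins had 6 genes, 4 higher and 2 lower, a median of 1.29 and the 99.7th percentile. The interval of that median reached down to -2.19. DREB2F (Os04g0648900) had 0.397 at 22 °C and 0.886 at 42 °C, and DREB2B (Os05g0346200) had 0.00387 and 0.108, whereas a DRE binding protein (Os01g0165000) had 0.130 and 0.0285. The 6 heat stress transcription factors had a median of 0.17 (69.2nd percentile). Os03g0854500, described as a heat shock transcription factor, had 0.205 and 0.179, with its transcripts going opposite ways, and HSFA2d (Os03g0161900) had 0.0150 and 0.0284. HSFA2 genes Os03g0745000 and Os10g0419300 and the coactivator MBF1c (Os06g0592500) were not analysed here.

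Histones package DNA, and 35 of the 39 genes in their list had higher scores at 42 °C, 8 of them at least 2-fold and none at least 2-fold lower. A single myb histone protein, Os01g0708000, is among the 39, and the other 38 had a median of 0.67. The median of the list was 0.65 (95% interval over genes 0.44 to 0.84; 99.97th percentile), against 0.27 in matched lists, and 0.39 when centred on genes with a mean of at least 0.2. Histone H1 Os04g0253000 went from 0.206 to 0.671, H2B Os01g0502900 from 0.716 to 1.62 and H4 Os05g0466600 from 0.350 to 0.791. Histone copies are near-identical, so reads may be divided between them.

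Lists for WRKY factors, jasmonate and glutathione S-transferases had high medians too. WRKY factors, which regulate stress and defence genes, had a median of 0.79 over 21 genes (interval -0.74 to 1.02; 99.92nd percentile). Of these 13 were higher and 8 lower, and 5 lay at least 2-fold higher and 5 at least 2-fold lower. WRKY45 (Os05g0322900) had 0.150 and 0.539 and WRKY74 (Os09g0334500) 0.159 and 0.322, but WRKY51 (Os04g0287400) 0.676 and 0.329. Jasmonate genes had a median of 0.65 over 24 genes (interval 0.09 to 0.92; 99.5th percentile), 20 higher, 5 of them at least 2-fold, and 4 lower, 3 of them at least 2-fold. The lipoxygenases Os10g0361000 and Os12g0559934, of the family that starts jasmonate synthesis, had 0.218 and 0.717, and 0.420 and 1.26. The Tify gene Os07g0615200 had 0.480 and 0.156, but it was the only lower gene among those described as Tify or ZIM. All the others were higher, among them Os10g0391400, named after its scores were seen (0.705 and 1.33). Jasmonate activity itself was not tested. Glutathione S-transferases, which conjugate toxic compounds to glutathione, had a median of 0.68 over 19 genes (interval -0.16 to 1.10; 99.0th percentile). Of these 14 were higher, 6 at least 2-fold, and 5 lower, 2 at least 2-fold, with Os10g0530900 at 0.349 and 0.829 and Os10g0525800 at 0.420 and 0.938. Among the 9 of these with a mean of at least 0.2 the list lay inside its range, at the 95.9th percentile. Centred on genes with a mean of at least 0.2, the medians of the WRKY, jasmonate and glutathione S-transferase lists were 0.53, 0.39 and 0.42.

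The word list for actins and tubulins, the subunits of the cytoskeleton, had a median of -0.62 over 27 genes (interval -2.04 to 0.06; 0.480th percentile). Without 2 genes of other kinds it was -0.62 over 25 (0.950th), with 17 lower, 10 of them at least 2-fold, and 8 higher. The median of the word list was -0.39 with each transcript on its own (2.95th percentile) and without transcripts of suffix 00 (4.00th), and -0.30 at a mean of at least 0.2 (3.65th), all inside the range. At a mean of at least 0.05 it was -0.39, outside it. The list's member past the minimum, Os06g0355150, from 0.583 to 0.229, is by its description a phosphatase named for suppressing an actin mutant. Actin 1 (Os03g0718100) had 0.271 and 0.298, a log2 ratio of 0.14 that turns negative when centred on genes with a mean of at least 0.2. Epidermis and cuticle genes, mostly lipid transfer proteins, had a median of -0.13 over 35 genes (interval -0.55 to 0.15; 1.18th percentile). They went both ways, 19 lower and 16 higher, with 7 at least 2-fold lower and 2 at least 2-fold higher. The median was -0.15 (0.450th) without 3 glycolipid transfer proteins. It was -0.36 with each transcript on its own (0.05th) and -0.04 among the 24 genes with a mean of at least 0.2 (0.650th), and centring on such genes set it to -0.40. The largest ratios past the minimum were those of lipid transfer proteins Os08g0532800, Os12g0115000 and Os07g0625800, which went from 0.664 to 0.0860, 0.970 to 0.249 and 0.712 to 0.244. Vascular genes (6 genes, 0.42, 78.7th percentile) and genes of dividing cells (10 genes, -0.04, 59.6th percentile) lay inside their ranges.

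Photosynthesis lists did not stand apart. Light-harvesting proteins (15 genes) had a median of 0.15 (40.1st percentile), photosystem and electron transport subunits (61 genes) 0.10 (8.66th) and Calvin cycle and photorespiration genes (25 genes) -0.08 (35.1st). Of the latter, 5 are chaperonins or a Rubisco large subunit entry, and the other 20 genes had -0.05 (40.7th). Over the 6 genes of the whole list with a mean of at least 0.2 the median turned to 0.22 (44.0th). The light-harvesting median was 0.36 with each transcript on its own (81.15th) and 0.47 with the lowest-numbered transcript (90.25th). At a mean of at least 0.2 it was 0.49 (84.55th), all inside the range. Photosystem subunits lay outside their range at a mean of at least 0.05 (0.07, 1.95th) and of 0.2 (0.07, 1.60th). The Rubisco small subunit gene Os12g0274700 had 0.339 and 0.515 and Rubisco activase Os11g0707000 had 0.148 and 0.141. Proteasome and polyubiquitin genes (46 genes, 0.38, 95.1st percentile), antioxidant enzymes (27, 0.35, 85.2nd), fermentation and submergence genes (33, 0.35, 91.0th), touch and calcium genes (38, 0.20, 72.4th) and ABA and LEA genes (39, 0.19, 83.6th) lay inside their ranges. Without 3 Rab GTPases the last had 0.09 (66.6th), and alcohol dehydrogenase 1 (Os11g0210300) had 0.195 and 0.260. The fermentation and submergence list was taken in largely by the words alcohol dehydrogenase. It holds, among others, a sinapyl alcohol dehydrogenase (Os10g0430200) and allyl alcohol dehydrogenases. No median without these was computed, so it says little of submergence genes. Splicing factors (52, 0.22, 96.2nd), mRNA decay genes (9, -0.12, 48.4th) and cell wall genes (27, -0.32, 23.2nd) also lay inside. The AP2/ERF word list (10, 0.48, 87.2nd) holds 3 genes of other kinds, and its other 7 had 0.60 (89.4th). With each transcript on its own it lay outside the range (0.82, 99.55th). The words also missed genes described by an ERF or AP2 domain, and a list of 23 with these, made after the scores were seen, had 0.73, above all random lists. Proteasome genes lay outside with each transcript on its own (0.42, 97.65th), with the lowest-numbered transcript (0.44, 98.05th) and at a mean of at least 0.2 (0.58, 97.9th). Splicing factors did without transcripts of suffix 00 (0.29, 98.3rd) and at a mean of at least 0.05 (0.48, 98.45th), and 5 cell wall genes at 0.2 (-0.63, 1.83rd). Centring on genes with a mean of at least 0.2 turned the medians of 6 lists inside their ranges negative: heat stress factors -0.10, light-harvesting -0.12, photosystem -0.17, touch -0.07, ABA -0.07 and splicing -0.05. In all, 13 of 32 lists stood apart, 8 low and 5 high, where about 1.6 would by chance if the genes of a list varied independently. Copies that share reads would break that condition, and some genes sit in more than 1 list. With 0.1 added to every score, which shrinks ratios of low scores, 11 of these 13 lists lay outside. Medians were then -0.25 for cytosolic ribosomal proteins, -0.52 for elongation factors, -0.38 for HSP70, -0.40 for HSP100 and chaperonins, 0.75 for DREB2 factors, 0.42 for WRKY factors, -0.28 for actins and tubulins and -0.05 for epidermis genes.

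**Figure D2:**
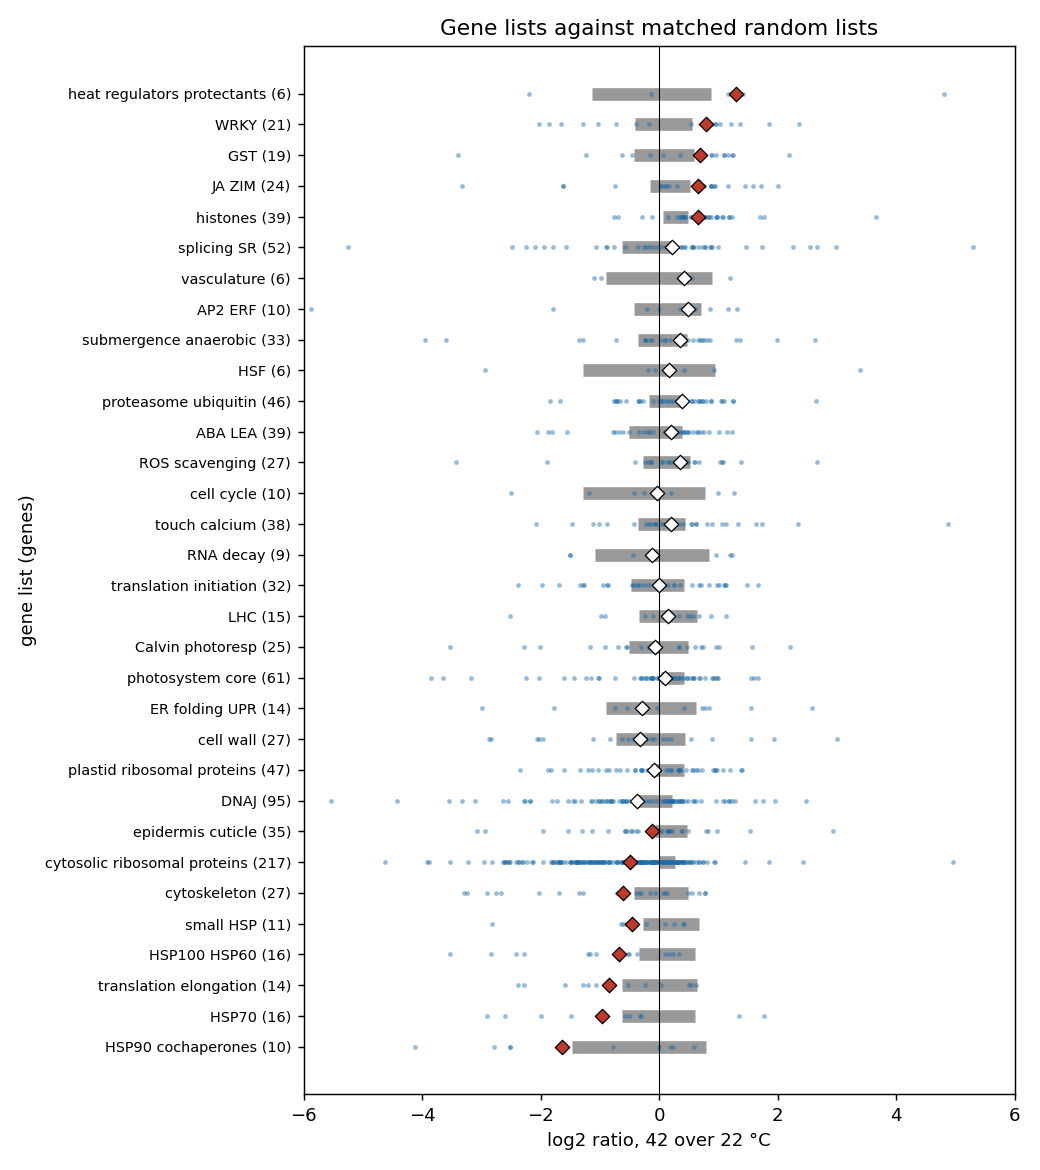
Log2 ratio of 42 over 22 °C (x) for each gene list (y, number of genes in brackets). Dots are genes, diamonds list medians (red where outside the range) and grey bars the 95% range of medians of 10000 matched random lists; 51 of 1047 members, at 0 at 1 temperature or beyond 6 on the log2 scale, are not drawn. The diamonds of 13 lists lie outside their bars.

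Among single genes past the minimum, the largest ratio towards 42 °C was that of an ERF-domain transcription factor, Os08g0408500, with 0.00522 at 22 °C and 0.472 at 42 °C. A set of 4 heavy metal transport/detoxification proteins followed among the first 10: Os02g0585200 (0.0305 and 0.489), Os02g0584800 (0.0672 and 0.530), Os03g0152000 (0.0804 and 0.533) and Os02g0584700 (0.109 and 0.666). The others were a RING/FYVE/PHD zinc finger protein (Os01g0972000), a bHLH protein (Os03g0741100), a thioredoxin-like protein (Os07g0684100), an Arm repeat protein (Os05g0476700) and a Myb protein (Os09g0538400), with log2 ratios of 3.16, 2.60, 2.45, 2.34 and 2.30. In the other direction a subtilisin-related peptidase, Os01g0868900, had 0.567 and 0.00664, an mRNA-binding protein, Os02g0316800, 0.806 and 0.0127, and a chalcone synthase, Os11g0530600, of flavonoid synthesis, 0.525 and 0.0137. A kinase activator of the Mps one binder kind (Os08g0163200), the PetM subunit of cytochrome b6/f (Os03g0765900), a sinapyl alcohol dehydrogenase (Os10g0430200) and an annexin (Os02g0753800) had log2 ratios of -4.05, -3.66, -3.59 and -3.59. A SWIB/MDM2 protein (Os12g0507500), a physical impedance induced protein (Os03g0103100) and a 2OG-Fe(II) oxygenase (Os08g0417000) had -3.40, -3.39 and -3.24. Os02g0584700, Os02g0584800 and Os02g0585200 share a description and have close locus numbers, so reads may be divided between them. Genes picked for extreme ratios of unreplicated scores overstate their differences on average.

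**Figure D3:**
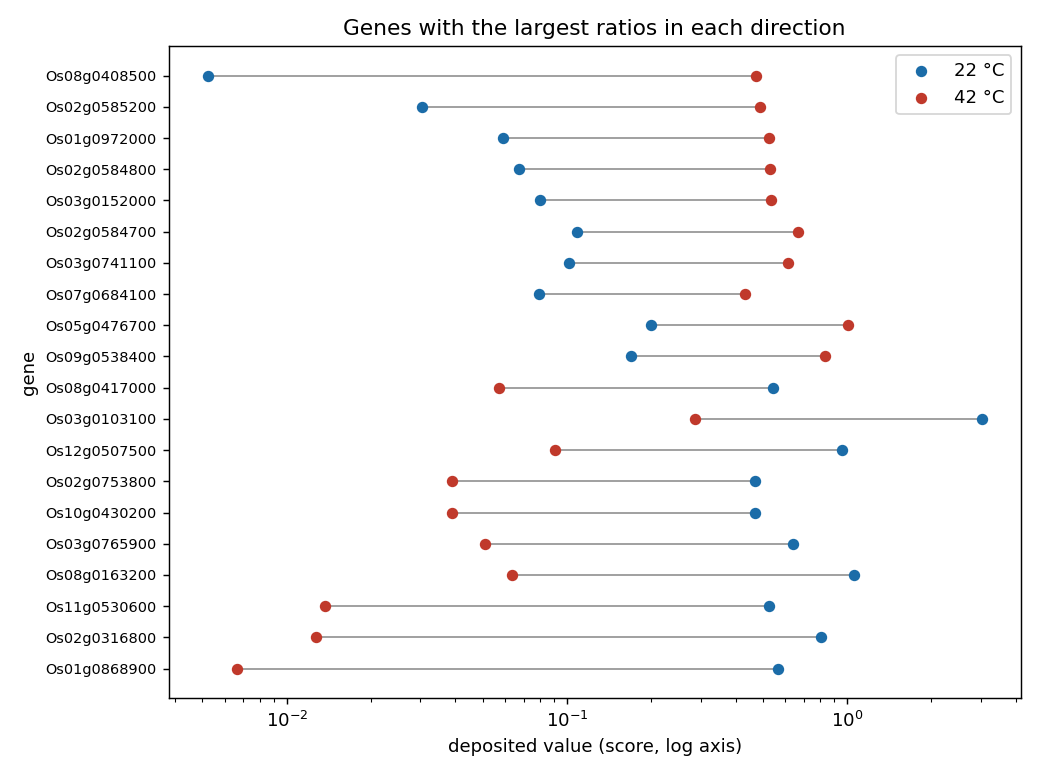
Score (x, log axis) at 22 °C (blue) and 42 °C (red) for the 20 genes with the largest ratios, 10 in each direction, among genes with a mean score of at least 0.234 (y, genes). The widest gaps are those of Os08g0408500, higher at 42 °C, and Os01g0868900, lower at 42 °C.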

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

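Minimum mean scores, the centring on genes with a mean of at least 0.2, the log2(1 + ratio) reading, the choices of transcript other than each on its own, the added 0.1, the wider AP2/ERF list and the removal of misfiled members were chosen after the data were seen. No paired analysis was possible because the table holds 1 pooled score per temperature; leaving out replicates, count tests and set tests over libraries could not be run for the same reason. Pseudocounts planned for abundance units and TMM were not run on these scores, rescaling by the median ratio is the centring on all genes, and leaving out abundant genes has no effect on scores that are not rescaled. With 0.1 added to every score, which shrinks ratios of low scores by construction, 255 genes were at least 2-fold higher and 273 lower, the median was -0.00054, and that of ribosomal proteins was -0.25. With a mean of at least 0.05, 866 genes were at least 2-fold higher, 897 lower and the median log2 ratio was 0.15; at 0.2 these were 337, 218 and 0.27, where fewer genes are counted. At 1.5-fold 2580 genes were higher and 2862 lower, and at 4-fold 497 were higher and 909 lower. With a score of at least 1 at both temperatures 0 genes were higher and 0 lower among 136 genes (median 0.15), at 5 also 0 and 0 among 6 (median 0.082), and at 10 no gene was left. Centring on all genes set the median to 0 by construction, and centring on genes with a mean of at least 0.2 set it to -0.24; the latter moved the medians of small heat shock proteins to -0.72, ribosomal proteins to -0.76 and histones to 0.39. Ribosomal proteins with a mean of at least 0.2 had -0.23, the cause not tested. Centrings move a list and its random lists alike and are left out of the next counts. None of the 13 lists that stood apart changed sign in 98 other recomputed medians, of which 87 lay outside the random range (2000 lists each). The 11 exceptions stand beside their lists in the report. At a mean of at least 0.2 the lists of HSP70, HSP90 and DREB2 factors had fewer than 5 genes. No median was computed for them at that minimum. Of the 98 medians 96 stayed within the interval over genes, but they reuse the same genes or part of them, and some intervals are wide. Sizes changed within these intervals: with 0.1 added, the HSP90 median went from -1.65 to -0.22 and that of HSP70 from -0.97 to -0.38. For the 19 lists inside their ranges, 12 of 135 medians moved outside and 11 changed sign. Of the 12, 11 are given in the report, and the other is the DnaJ word list with each transcript on its own (-0.44), clone-named genes included. Unknown depth limits every ratio of low scores.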

Other observations

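The groups below were picked after the data were seen, from 779 words and word pairs of the descriptions. Of these, 77 had medians outside the 95% range of 300 matched random lists each. About 39.0 would by chance if genes that share a word varied independently, which copies with shared reads would break. Of 22 heavy metal transport/detoxification proteins, small proteins with a metal-binding domain, 21 had higher scores at 42 °C and 9 at least 2-fold, with a median log2 ratio of 0.72 (95% interval over genes 0.28 to 1.28; 99.8th percentile of 10000 lists). Harpin-induced proteins, a family named for a bacterial elicitor of defence, had a median of 0.99 over 16 genes, 11 higher and 5 lower (-0.68 to 1.39), with Os12g0119800 at 0.253 and 0.714. Cupredoxins, copper-binding proteins, had 0.89 over 10 genes, 8 higher and 2 lower (-0.24 to 1.73; 99.5th percentile). RabGAP/TBC proteins had 0.95 over 11 genes, 6 higher and 5 lower (-1.32 to 2.96; 99.0th). Cytochrome P450 enzymes had 0.27 over 51 genes, 29 higher and 22 lower (-0.24 to 0.81; 97.7th). Median scores at 22 and 42 °C were low, 0.0305 and 0.0387 for RabGAP/TBC proteins and 0.0578 and 0.0610 for cytochrome P450 enzymes. Ratios of such low scores spread widely.

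FAS1-domain proteins, a domain of cell surface adhesion proteins, had a median of -1.21 over 10 genes, 8 lower and 2 higher (-2.16 to 0.40), below all random lists; Os08g0321000 had 0.513 and 0.114. Aspartic peptidases of family A1 had -1.27 over 11 genes, 10 of them lower (-5.16 to -0.39; 0.180th percentile), with Os09g0482200 at 1.05 and 0.424 and Os09g0482500 at 1.14 and 0.471. Proteins with a no apical meristem domain had -0.87 over 14 genes, 9 lower and 5 higher (-1.92 to 0.92; 0.420th percentile): Os12g0477400 had 0.648 and 0.234, but Os02g0579000 0.180 and 0.443. Proteins described as mitochondrial had -1.17 over 21 genes, 17 of them lower (-2.20 to -0.05; 0.210th). Their median scores were 0.0867 at 22 °C and 0.0279 at 42 °C.

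All tests below but the one on RNA were chosen after the values they measure had been seen. Of the 30 highest transcripts at 22 °C, 29 carry the suffix 00, which 6.54% of transcripts carry. The 5 entries described as the Rubisco large subunit, a plastid gene, scored between 5.07 and 9.41 at 22 °C, with a mean log2 ratio of -0.36 and an SD of 0.035 between them. Random sets of 5 from a pool of 100 transcripts had a median SD of 0.43, and 0.01% had one as small. The lowest of the 5 entries ranks 12th at 22 °C, so most of the 100 scored below all of them there. Ratios of lower scores spread more widely, so the comparison may overstate how unusual the small SD is. A candidate explanation is that reads of the plastid gene were shared among these loci, in which case the scores describe the plastid gene or its copies, and not 5 separate genes; no biological explanation was tested.

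The lower scores of cytosolic ribosomal protein genes at 42 °C could come from the processing. A scale that differs between temperatures moves all genes alike, yet the list lay -0.64 from its matched random lists on the log2 scale. This distance is the one by which the list already stood apart, so it is no further test. Noise of low scores would spare well-scored genes, yet the 114 with a mean of at least 0.2 had a median of -0.23 against 0.24 in random lists, below all of them. A high ratio need not rest on many reads and the depths are unknown, so noise from few reads stays open. Reads divided between paralogs stay open: the median over 76 protein names was -0.44 after averaging paralogs, but averaging ratios does not undo reads assigned to another copy. A change in RNA, with footprints unchanged, stays open too, since 0 columns give footprints or RNA apart, as does an effect of temperature on translation, which 1 pooled score per temperature cannot test.

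Low scores spread more widely than high ones, the interquartile range of log2 ratios falling from 3.47 in the lowest 10% of genes to 0.66 in the highest, and 480 genes were at 0 at 42 °C alone against 234 at 22 °C alone. Fewer footprint reads at 42 °C may account for the larger number of genes at 0 there. The spread of low scores rests on ratios that hold both temperatures and could come from few reads at either. With genes ordered by their score at 22 °C, the log2 ratio of summed scores in the highest of 3 equal parts minus that in the middle part was -0.093 (bootstrap 95% interval -0.14 to -0.04). Noise at 22 °C alone lowers that value, so the test leaves the depth explanation open, and it cannot be told apart from a temperature effect on weakly translated genes without the depths.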
